A study of Mus musculus with 7 samples.

How the data were processed

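Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on myotubes, the multinucleated fibres that muscle precursor cells form in culture. Per the labels' protocols, primary satellite cells of wild-type C57BL/6 mice were differentiated in medium with 5% horse serum and transduced overnight at a multiplicity of infection of 100 with an adenovirus encoding Flag-tagged Zfp697, a zinc finger protein. Crosslinking used 1% formaldehyde for 12 minutes, and chromatin was sheared by 5 sonication cycles of 30 seconds on and 30 seconds off. The series has 7 samples: 3 immunoprecipitations with an antibody against the Flag tag (called FLAG 1 to 3), 3 with control immunoglobulin (IgG 1 to 3) and 1 input. The labels disagree on the control, since the sample titles and the design text give mouse IgG and the antibody field gives normal rabbit IgG, so the group is called IgG here. The input served as control for peak calling; a peak list of the input itself was not analysed here.

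The 6 deposited files are peak lists, 1 per library, and replicates were not pooled. Per the file headers, the authors called peaks with MACS 3.0.0a7 from deduplicated paired-end alignments, in the mode that piles up whole fragments, with summit splitting, a q-value threshold of 0.1 and a genome size of 1870000000 bp, and each antibody library was compared with the same input of 46438560 fragments. The submitters' processing notes name STAR, MACS3 and bedtools and the genome build GRCm38.p6; the order of these steps is not given in the sources used here. Per the file headers, the pileup of each summit is a fragment coverage signal that was not scaled to sequencing depth. The deposited −log10 p and −log10 q values come from the authors' test of the summit against the local background from the input. The deposited fold enrichment is a linear ratio of the summit pileup over that background, and it is used here to describe, rank and filter peaks.

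Each row of the lists is a summit, and rows that repeat an interval were joined into 1 peak. The peak carries the highest fold, pileup, −log10 p and −log10 q over its summits, each taken separately. Libraries held between 14.3 and 40.4 M fragments (M, 1000000), and this depth sets how weak an enrichment could be called. The local background of a summit was derived from its pileup and fold with the caller's pseudocount of 1. Its lowest value in each library lay within 2% of the level given by the fragment number, the fragment size and the genome size, and it is called the genome-wide minimum. Peaks of the 6 libraries were merged into union regions where they shared at least 1 bp, and a library held a region where at least 1 of its peaks overlapped it. Overlap between libraries was the Jaccard index, the shared length over the joint length. Random placement moved each peak within its chromosome's range, 100 times for regions and 10 times for pairs of libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

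Genes came from a RefSeq gene table of GRCm38.p6, the build of the files, with 49943 genes. The table gives gene ends without strand or exons, so the planned share of peaks near a transcription start site was replaced by the share of peaks centred within 1 kb of either annotated gene end. Motif content, base composition, repeats and exon positions were not analysed here.

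FLAG and IgG were compared by exact two-sided permutation tests on per-library values. With 3 libraries against 3 such an exact test cannot go below p = 0.1, so no group difference could pass 0.05. Nothing in the labels says that replicates came from separate cultures or animals, so these p-values measure only the spread between the samples, which may be technical. The test of Jaccard indices went over the 20 ways to choose 3 of 6 libraries, with a smallest one-sided p of 0.05. Before the data were examined, 9 gene lists with 188 genes were fixed, covering sarcomere and contraction, myogenic regulators and fusion, inflammation and chemokines, extracellular matrix and remodelling, interferon and antiviral response, highly transcribed housekeeping and small RNA genes, and markers of fibroblasts, of macrophages and leukocytes, and of endothelium. They were tested with Fisher's exact test, two-sided, over 3 classes of regions, with Benjamini-Hochberg adjustment over 27 tests. All 188 genes were placed.

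The rule for named regions, also fixed before the data were examined, took any region within 5 kb of Zfp697, Mir206 or Mir133b, up to 10 regions held by all 3 FLAG and no IgG library, and up to 5 each of the regions held by all 3 IgG and no FLAG library and by all 6 libraries, ranked by the lowest fold over the libraries of the class. Named genes were those that such a region overlaps or lies nearest to, and listed genes with a region of all 3 FLAG and no IgG library or of all 6 within 1 kb of an end. Alternatives were stricter thresholds of −log10 q and of fold (both at least 5), equal list lengths, chromosomes 1 to 19, X and Y only, removal of peaks that overlap all 3 IgG libraries, each library left out, a replicate block, 50% reciprocal overlap, windows of 100 bp on each side of the summit, other replicate requirements, a window of 5 kb and the mean log2 fold. Added after the data were seen were each summit counted, peaks per M fragments, peaks under 10 kb, and joining of regions within 50 kb. The region code was tested on simulated peak lists for the 6 libraries and recovered 90 of 90 regions planted in all 6, 197 of 200 planted in all 3 FLAG libraries alone and 50 of 50 planted in all 3 IgG libraries alone. Each region was planted in every library of its class, shifted by at most 100 bp. Missed calls, unequal depth and clustered peaks were not simulated, so this checks the code only.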

Results

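Zfp697, a zinc finger protein that the series title describes as RNA-binding and as acting in muscle inflammation and remodelling, was expressed with a Flag tag in mouse myotubes, and its contact with chromatin was assayed by Flag ChIP-seq beside control IgG. Peak lists of 3 FLAG and 3 IgG libraries were analysed. FLAG 1, 2 and 3 held 14.3, 40.4 and 40.0 M fragments (M, 1000000), and IgG 1, 2 and 3 held 30.4, 19.9 and 30.2 M. All 6 lists were called against the same input of 46.4 M fragments, and a shared control by itself can raise the overlap between lists above that of random placement.

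The first comparison asked whether the Flag antibody recovered more or stronger peaks than IgG. FLAG libraries held 2257 ± 735 peaks (SD, n = 3) and IgG libraries 1512 ± 490 (SD, n = 3), a ratio of 1.48. Strong peaks, with a fold enrichment of 5 or more, numbered 47.3 ± 7.64 in FLAG and 46.0 ± 7.0 in IgG (SD, n = 3 each). Nearly all of them were 10 kb or wider. Only 1 to 2 per FLAG library and 2 to 4 per IgG library were narrower, so the counts say little about narrow strong peaks. The median fold enrichment was 2.46 ± 0.384 in FLAG and 2.61 ± 0.194 in IgG (SD, n = 3 each), and the highest fold of any peak was 52.1, in IgG 1.

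The peak numbers of single libraries overlapped, from 1420 to 2794 in FLAG and from 1160 to 2072 in IgG. Exact permutation tests, two-sided, gave p = 0.2 for peak number, p = 0.8 for strong peaks and p = 0.6 for median fold, where 3 libraries against 3 allow no p below 0.1. Peaks covered 18.7 ± 4.19 Mb in FLAG and 14.6 ± 2.56 Mb in IgG (SD, n = 3 each; exact permutation p = 0.3). Most of that length lay in few wide peaks: peaks of 10 kb or more made up 7.95 to 10.5% of the peaks of a library and 80.1 to 86.6% of its covered length. Peak number moved with sequencing depth across the 6 libraries, with Pearson's r = 0.845 (exact permutation p = 0.0458, adjusted 0.0583 over 2 statistics) and Spearman's rho = 0.829 (exact permutation p = 0.0583, adjusted 0.0583). Without FLAG 1 and IgG 2, the libraries farthest from the median depth, r was 0.876 over 4 libraries (exact permutation p = 0.125). Per M fragments, FLAG libraries held 77.5 ± 19.2 and IgG libraries 56.6 ± 12.6 peaks (SD, n = 3 each; exact permutation p = 0.2).

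**Figure D1:**
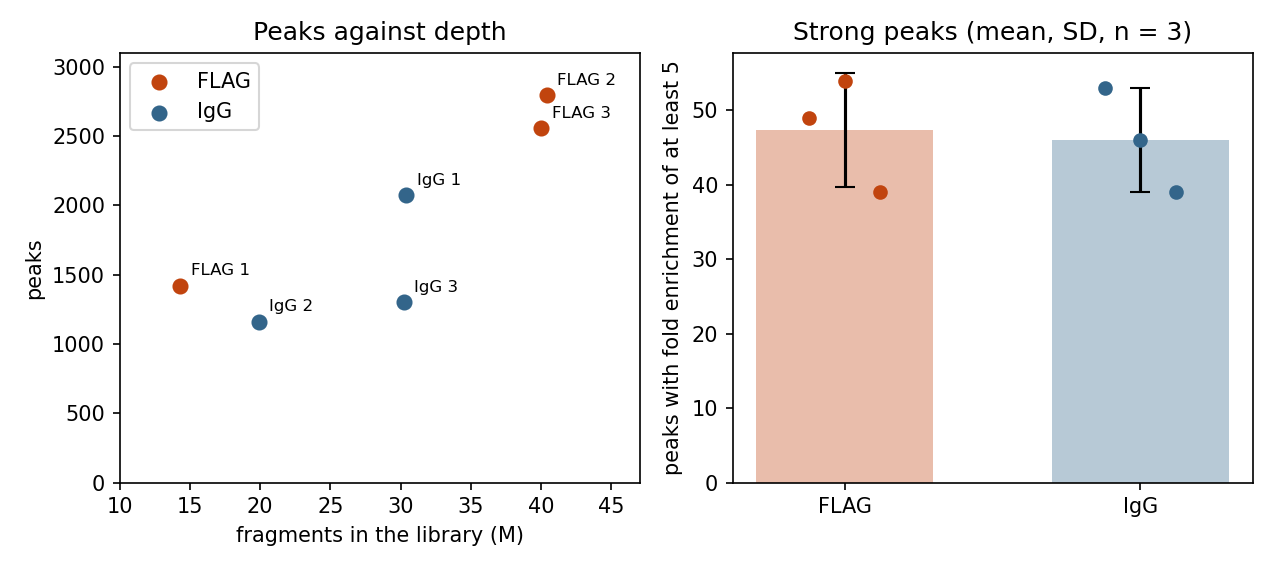
Left, the number of peaks of each library against its fragments in M, with FLAG libraries in orange and IgG libraries in blue. Right, the number of peaks with a fold enrichment of at least 5, as points per library, group means as bars and SD (n = 3) as error bars; the means were 47.3 in FLAG and 46.0 in IgG.

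The second comparison asked which places were recovered by the Flag antibody in every replicate and never by IgG. There were 6 such regions, all weak, with folds from 2.05 to 3.66. A pair of them lay inside Rora, a gene for a nuclear receptor, on chromosome 9 (GRCm38.p6) at 68953454 to 68979484, with folds of 2.68, 2.36 and 3.04 in FLAG 1, 2 and 3, and at 68931035 to 68943991, with folds of 2.68, 2.16 and 2.71. One on chromosome 1, at 172563439 to 172583957, overlapped Vsig8 and Slamf8, the latter a receptor of the SLAM family on myeloid cells, with folds of 3.66, 2.06 and 2.95. One on chromosome 19, at 13405649 to 13413018, overlapped the olfactory receptor gene Olfr1469, with folds of 2.68, 2.55 and 2.05.

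The remaining regions of this class lay on chromosome 8 outside annotated genes. The region at 20534971 to 20536763 was 12582 bp from the predicted gene Gm40469 and had folds of 2.90, 2.45 and 2.53, and the region at 96638150 to 96640727 was 234068 bp from Gm32122 and had folds of 3.12, 2.65 and 2.38. Both had peaks of IgG libraries within 50 kb, from 2 and from 1 library, and the regions at Rora, Slamf8 and Olfr1469 had none. Within Rora, 22 union regions spanned 248 kb, of which FLAG 1 held 7, FLAG 2 held 4, FLAG 3 held all 22, and the IgG libraries held 0, with folds of 2.06 to 3.04.

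The mirror class, held by all 3 IgG and no FLAG library, had 0 regions. With every list shortened to 1160 peaks the counts were 3 in the FLAG class and 2 in the mirror class, and with peaks under 10 kb alone, an alternative chosen after the data were seen, the direction turned, to 5 and 12. Random placement of the same peaks gave a median of 2 and at most 6 regions in the FLAG class. Of the 20 ways to choose 3 of the 6 libraries, 10 gave 6 or more regions held by those 3 alone, the FLAG choice included, and FLAG 2, FLAG 3 and IgG 1 together gave 50, the highest number. These 3 libraries had the most fragments and peaks, and FLAG 1 had the fewest fragments. Choices that included FLAG 1 gave 0 to 7 regions. The 20 choices thus differ in depth and are not an even chance level. Depth alone did not order them, since FLAG 2, FLAG 3 and IgG 3 gave 12. IgG 3 held 30.2 M fragments and IgG 1 held 30.4 M. FLAG 2 and IgG 1 shared 134 regions held by no other library, and FLAG 2 and FLAG 3 shared 108. The 6 regions fell to 0 at −log10 q of at least 5 and to 0 at a fold of at least 5. Leaving out FLAG 1, 2 or 3 gave 114, 78 or 25 regions and leaving out IgG 1, 2 or 3 gave 13, 14 or 11, since fewer libraries then had to hold or lack a peak.

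**Figure D2:**
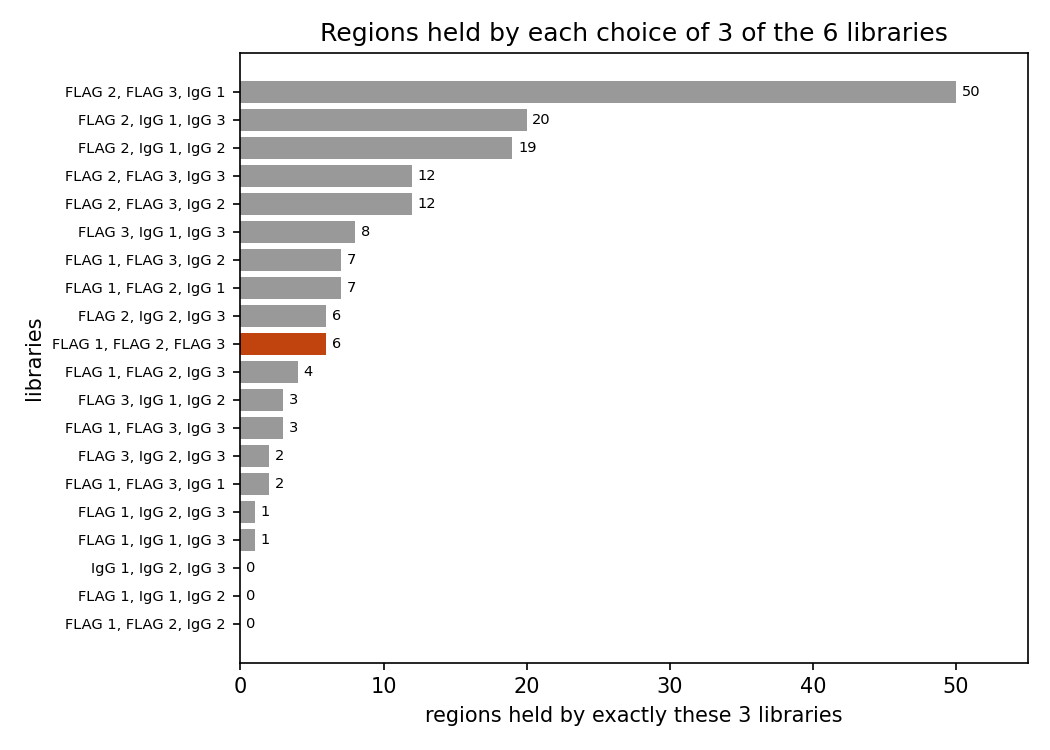
Number of union regions held by exactly 3 libraries, for each of the 20 choices of 3 from the 6 libraries, with the FLAG choice in orange. The FLAG choice gave 6 regions and the choice of FLAG 2, FLAG 3 and IgG 1, the libraries with the most fragments, gave 50.

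With a peak required in at least 2 FLAG libraries and in no IgG library, there were 194 regions, against a median of 58 and at most 72 under random placement, and the mirror count for IgG was 33. Lists filtered before merging, in which weaker IgG peaks no longer exclude a region, gave 20 and 2 regions at −log10 q of at least 5. That threshold is easier to reach in a deeper library. In the region on chromosome 8 at 20534971, FLAG 1 had −log10 q of 1.72 at a fold of 2.90, and FLAG 3 had 3.94 at 2.53. At a fold of at least 5 the filtered lists gave 3 and 2, which are not among the 194. The contrast was smaller with peaks under 10 kb alone, at 224 and 146, and it turned without FLAG 2, at 78 and 100, and without FLAG 3, at 25 and 53, where both remaining FLAG libraries but only 2 of the 3 IgG libraries had to hold a region; without FLAG 1 it was 114 and 35. None reached a fold of 5, the highest being 4.91. They were clustered: with gaps up to 50 kb they formed 71 runs, and the longest, on chromosome 1 at 58489138 to 58608966, held 24 of the 194. That run is named outside the rule for named regions. It covered Orc2, which encodes a subunit of the origin recognition complex, Ndufb3, which encodes a subunit of respiratory complex I, and Fam126b. Its folds were 1.97 to 2.75 in FLAG 2 and FLAG 3, with no peak of FLAG 1. With regions within 50 kb joined, 30 loci were held by at least 2 FLAG libraries and no IgG library, and 9 by at least 2 IgG libraries and no FLAG library. With every list shortened to 1160 peaks, these counts were 84 and 43 over single regions, and 15 and 12 over joined loci.

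The third comparison asked which places both antibodies recovered. The strongest peak of every library by fold was of this kind. Of 5937 union regions, 94 were held by all 6 libraries, against a median of 2 and at most 4 under random placement. They had a median width of 85.0 kb and a total width of 13.1 Mb. Peak length inside them made up 66.4 ± 10.1% of the covered length of FLAG libraries and 80.4 ± 8.98% of that of IgG libraries (SD, n = 3 each). Of the 94 regions, 61 reached a fold of 5 in at least 1 library.

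The region ranked first lay on chromosome 2 at 98672303 to 98935247, overlapped only the predicted gene Gm33780, and had folds of 32.8, 44.5 and 37.3 in FLAG 1, 2 and 3 and 52.1, 44.6 and 41.2 in IgG 1, 2 and 3. A second region on the same chromosome at 98371844 to 98657262, over the predicted gene Gm13806, had folds of 21.4 to 34.9. The region on chromosome 15 at 35459494 to 35583997 lay inside Vps13b, a gene for a lipid transfer protein of the Golgi, with folds of 22.3 to 26.7. On chromosome 14, the region at 8150032 to 8286578 covered Pdhb, which encodes a subunit of pyruvate dehydrogenase, Acox2, which encodes a peroxisomal acyl-CoA oxidase, and Pxk and Kctd6, with folds of 16.6 to 23.5. On chromosome 17, the region at 13306599 to 13547182 covered Tcp10c and had folds of 15.8 to 31.0. The fold at the 94 regions did not separate the antibodies. Per-library medians of log2 fold averaged 2.22 ± 0.08 in FLAG and 2.19 ± 0.10 in IgG (SD, n = 3 each), a difference of 0.03 (exact permutation p = 0.8, two-sided). All FLAG values lay above all IgG values at 2 regions and below them at 3, where chance gives 4.70 in each direction (5% of 94).

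**Figure D3:**
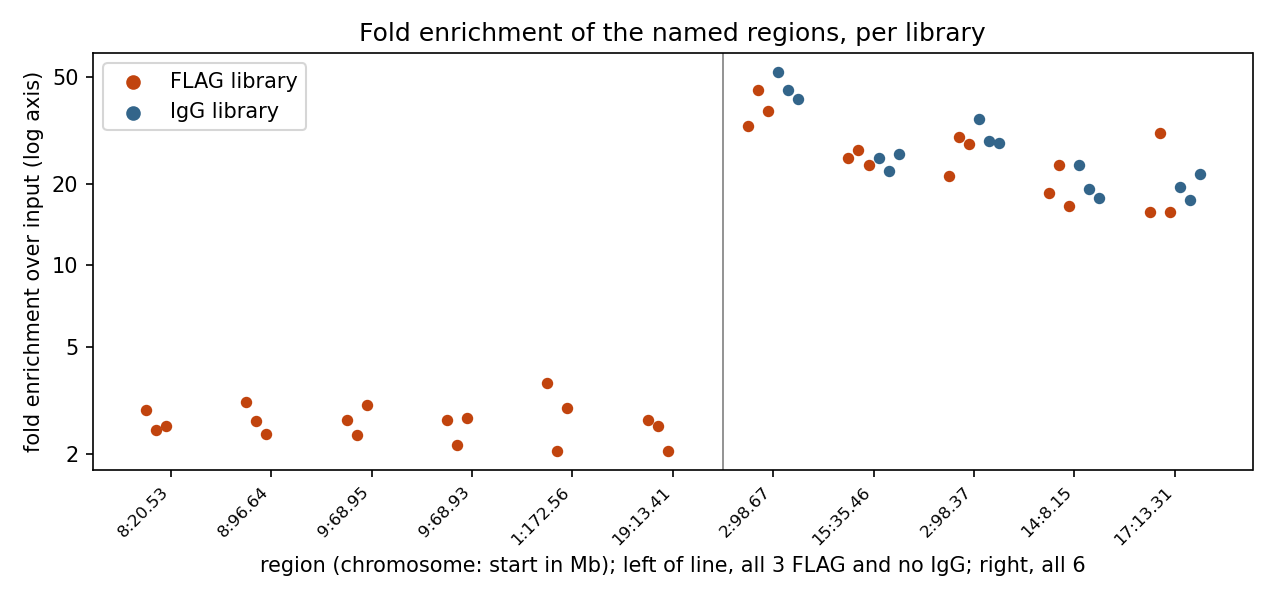
Fold enrichment over input (log axis) of the 6 regions held by all 3 FLAG and no IgG library, left of the line, and of the 5 highest ranked regions held by all 6 libraries, right of it, with a point per library that held the region. The first set lies between 2.05 and 3.66 and the second between 15.8 and 52.1, with FLAG and IgG points intermixed.

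Within the region ranked first, the pileup fell from its start to its end in all 6 libraries, from 451 to 22 fragments in FLAG 2 and from 376 to 17 in IgG 1, with Spearman correlations of −0.998 to −0.999 between pileup and position across summits, which are not independent.

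**Figure D4:**
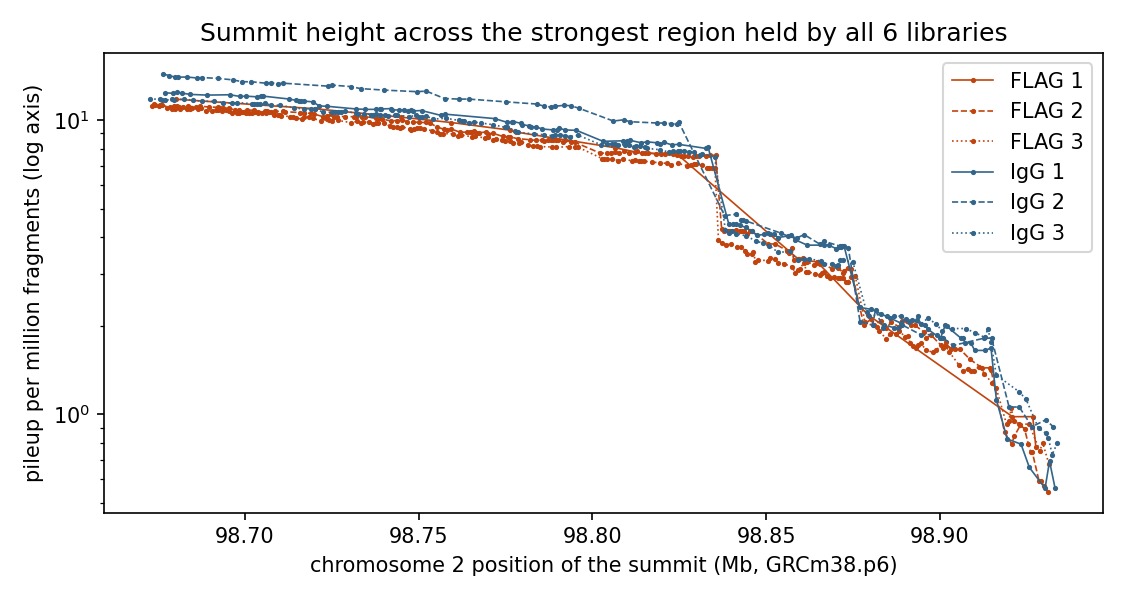
Pileup per M fragments (log axis) of each summit in the top-ranked region held by all 6 libraries, against its position on chromosome 2 in Mb of GRCm38.p6, with a line per library, FLAG in orange and IgG in blue. All 6 lines fall from left to right, with Spearman correlations of −0.998 to −0.999.

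Sharing between whole lists was no closer within FLAG than between FLAG and IgG. The Jaccard index averaged 0.509 over the 3 FLAG pairs (0.463 to 0.542), 0.616 over the 3 IgG pairs (0.562 to 0.654) and 0.574 over the 9 pairs of FLAG and IgG (0.508 to 0.676). The closest pair of all was FLAG 2 with IgG 1. The within-FLAG mean minus the FLAG-to-IgG mean was −0.0648, with p = 1 in the planned one-sided exact permutation test and p = 0.15 two-sided. Random placement gave at most 0.0101 for any pair. Of the 149 regions held by all 3 FLAG libraries, 143 (96.0%) were also held by at least 1 IgG library. By number, most regions were not shared at all, with 4970 of the 5937 regions (83.7%) held by a single library.

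At Zfp697 itself, the gene carried by the adenovirus, the peak was higher in the IgG than in the FLAG libraries that held it. Zfp697 spans 98381962 to 98431951 on chromosome 3, and the only union region in it lay at 98425287 to 98427476; whether this is exonic was not analysed here. The fold was 1.51 in FLAG 2 and 1.99 in FLAG 3, against 2.69 in IgG 2 and 6.04 in IgG 3, and FLAG 1 and IgG 1 had no peak there. Per M fragments, the pileup was 16.9 in FLAG 2, 27.5 in FLAG 3, 36.2 in IgG 2 and 75.9 in IgG 3. The local background from the input stood at 49.3 times its genome-wide minimum in these 4 libraries. All 4 lists were called against the same input, so this is 1 measurement of the input. No region of any library lay within 5 kb of Mir206 or Mir133b, a neighbouring pair of muscle microRNA genes on chromosome 1.

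**Figure D5:**
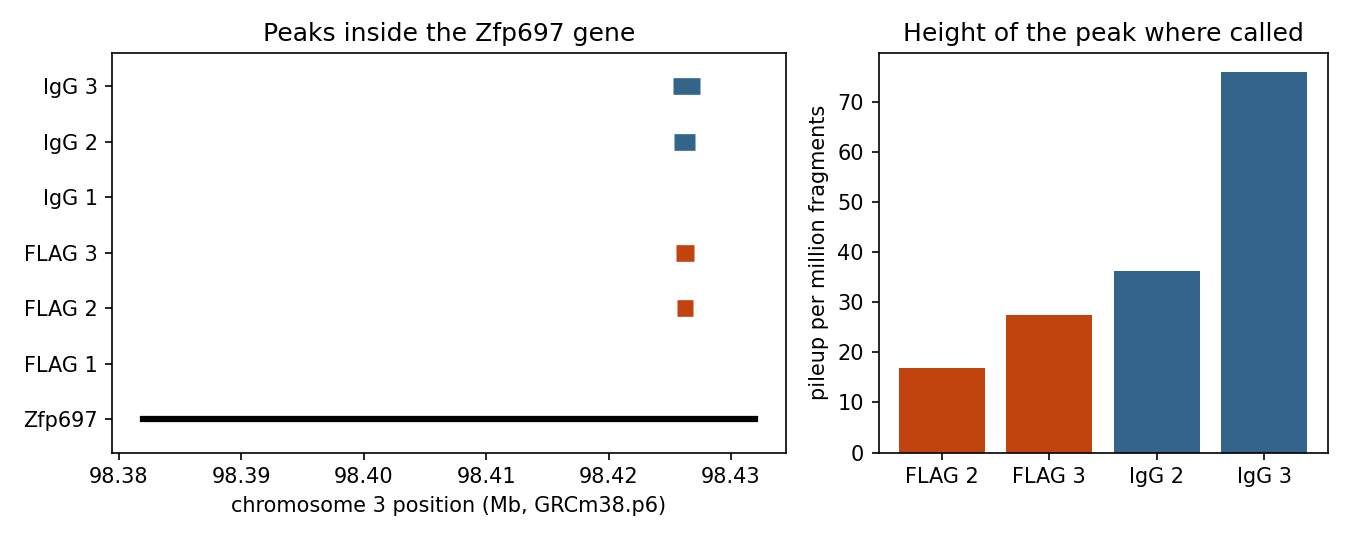
Left, extent of the peak called in each library inside the Zfp697 gene (black line) on chromosome 3 in Mb of GRCm38.p6, FLAG in orange and IgG in blue. Right, pileup of the peak per M fragments in the 4 libraries that held it, from 16.9 in FLAG 2 to 75.9 in IgG 3.

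The last comparison asked whether peaks lay at gene ends and at genes of muscle, inflammation or other programmes. In FLAG libraries 5.45 ± 1.04% of peaks were centred within 1 kb of an annotated gene end, and in IgG libraries 6.66 ± 1.22% (SD, n = 3 each; exact permutation p = 0.2, two-sided). Randomly placed peaks gave 6.00% and 6.01%. Shares of single libraries ran from 4.65% in FLAG 1 (95% Wilson interval 3.67 to 5.87%) to 7.87% in IgG 1 (6.78 to 9.11%), intervals that cover counting error only. At −log10 q of at least 5 the direction turned, with FLAG 0.767 percentage points higher (exact permutation p = 0.7).

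None of the 188 fixed genes had a region of all 3 FLAG and no IgG library, or of at least 2 FLAG and no IgG library, within 1 kb of an end, where 0.011 and 0.17 genes were expected from all 49943 genes. Near regions held by all 6 libraries there was 1, Ly6a, a surface antigen gene of the fibroblast list, where 1.1 were expected, and there were 0 with peaks under 10 kb alone. Ly6a lies in a region on chromosome 15 at 74917198 to 75081315 that also covers Ly6c1, Ly6e and Ly6i, with folds of 9.37, 14.2 and 12.3 in FLAG 1, 2 and 3 and 10.3, 10.8 and 9.57 in IgG 1, 2 and 3. For the fibroblast list, 1 of 10 genes gave p = 0.059 in Fisher's exact test (adjusted p = 1). The counts were 0 of 35 for sarcomere and contraction, 0 of 26 for myogenic regulators and fusion, 0 of 29 for inflammation and chemokines, 0 of 24 for extracellular matrix and remodelling, 0 of 22 for interferon and antiviral response, 0 of 22 for highly transcribed housekeeping and small RNA genes, 0 of 12 for macrophage and leukocyte markers and 0 of 8 for endothelial markers. None of the 27 Fisher tests had an unadjusted p under 0.05. Over regions of any library, Ly6a was again the only fixed gene, 1 of 188 against 3.18 expected (Fisher's exact test, two-sided, p = 0.385).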

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

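The tests in this part were chosen after the values at Zfp697 had been seen. The input has no comparison of its own in the report, and the background derived from it at the Zfp697 peak stood at 49.3 times its genome-wide minimum. Flag-Zfp697 bound at its own gene as the whole origin of the peak is argued against by the peak's height, since the mean pileup per M fragments in the 2 FLAG libraries that held it was 0.396 times that in the 2 IgG libraries, and both FLAG values lay below both IgG values. A candidate explanation is Zfp697 DNA carried by the adenovirus and recovered with every antibody and in the input, which the value of 49.3 and the narrow extent within the gene are consistent with. A smaller contribution of true binding stays open, because the amount of viral DNA in each library was not measured. With groups of 3 libraries, no library was tested as standing apart from its group.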

How the results depend on the processing

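Peak number, covered length and median fold kept their direction under all 14, 13 and 14 alternatives, and so did the Jaccard difference under 15. With 3 libraries against 3 no p could pass 0.05, so this speaks of direction only. The Jaccard difference moved in size, from −0.0648 to −0.0011 without peaks that overlap all 3 IgG libraries and −0.00825 with peaks under 10 kb. It was −0.00544 with 50% reciprocal overlap, −0.00999 with summit windows and −0.0727 at −log10 q of at least 5. The median fold difference went from −0.157 to −0.0157 with equal list length and −0.31 at −log10 q of at least 5. The share of peaks near a gene end reversed at −log10 q of at least 5, where FLAG was 0.767 percentage points higher, and kept its direction under the other 13; the cause was not tested. The 6 regions of all 3 FLAG and no IgG library moved most: 0 at −log10 q of at least 5, 0 at a fold of at least 5, 3 with equal list length, 88 with summit windows, 194 with at least 2 FLAG libraries and 24 with at most 1 IgG library allowed. The last 2 follow from a weaker requirement. Summit windows can split a wide region into many, but how many of the 88 arose in this way was not counted. Leaving out 1 library gave 11 to 114 such regions, log2 ratios of 0.381 to 0.870 for peak number and 0.228 to 0.540 for covered length, differences of −0.378 to −0.036 in median fold and −0.123 to −0.0265 in Jaccard index, and −1.82 to −0.604 percentage points at gene ends. Of the alternatives added after the data were seen, each summit counted and peaks per M fragments kept the direction of peak number, and peaks under 10 kb that of all 5 differences. Peaks under 10 kb and regions within 50 kb joined gave 5 and 5 FLAG regions, but with peaks under 10 kb the mirror class of all 3 IgG and no FLAG library rose from 0 to 12, above the FLAG count; the cause was not tested. The count of fixed genes stayed at 0 near both FLAG classes under the 14 alternatives run for each. With only 0.011 and 0.17 genes expected in the main setting, that says little. Near regions of all 6 it stayed at 1 under 12 of 13, with 0 for peaks under 10 kb, since the region at Ly6a is 164.1 kb wide. The count near regions of all 6 was left out for the alternative without peaks that overlap all 3 IgG libraries, since that filter removes peaks of this class. The lists hold only chromosomes 1 to 19, X and Y, so that alternative moved nothing, and equal list length gives no value for peak number.

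The labels do not say whether replicate numbers pair the libraries, and they were not treated as pairs, since not every same-numbered correlation was above 0.1: over the 94 regions of all 6, same-numbered libraries' deviations from their group means correlated at r = 0.168, 0.0426 and 0.147. Each library correlated best with its own number, but FLAG 2 only by 0.0426 against 0.0235 with IgG 3. Whether this order exceeds chance was not tested, so nothing is concluded from it about pairing. With the replicate block, the log2 ratio of peak number was 0.565 (exact sign-flip permutation p = 0.5, smallest possible 0.25), the Jaccard difference −0.0317, and 14 regions were held by all 3 FLAG libraries once each had lost, before merging, the peaks that overlapped a peak of its same-numbered IgG library, against 6 without the block. These p-values could not have passed 0.05. Depth bounds how weak a peak could be called, with 14.3 M fragments in FLAG 1 and 40.4 M in FLAG 2.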

Other observations

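All tests in this part were chosen after the data had been seen, except the single-region test of list length and the count of splits for regions in at least 2 FLAG libraries. A region held by all 6 libraries lay over a gene cluster and is named here after its values were seen. On chromosome 4, a region of 2199 kb at 145394634 to 147594008 covered a cluster of zinc finger genes, among them Zfp600, Zfp978 and Zfp993, with folds of 14.4 to 20; it also covered vomeronasal receptor pseudogenes and is 1 of the regions counted for that family.

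A hypothesis was that the regions held by all 6 libraries lie over clustered gene families more often than random places of the same widths. Of 136 families with 20 or more genes sharing a symbol prefix, 2 passed an adjusted p of 0.05 in 10000 random placements. Vomeronasal receptor genes and pseudogenes (Vmn) were met by 6 of the 94 regions against 0.85 on average (permutation p = 0.0003, adjusted 0.02). The 6 regions lay on chromosomes 4, 16, 17 and 18. The pair on chromosome 17 was adjacent, at 23289381 to 23294341 and at 23294556 to 23479050, and both met Vmn2r114. Random placement moved each region separately, so this place counts as 2 regions and the p-value overstates the evidence. The region on chromosome 16 and that of 2199 kb on chromosome 4 met pseudogenes only. Fibroblast growth factor genes were met by 3 regions against 0.15 (permutation p = 0.0003, adjusted 0.02), all inside the 1 gene Fgf13 on the X chromosome, so that call speaks of a single place. The zinc finger (Zfp) genes did not pass, with 3 regions against 1.6 on average (permutation p = 0.23, adjusted 1). A first run with a smaller number of placements gave no family under 0.05, its smallest p being too coarse for 136 families, and the number was then raised.

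The first pattern weighed is the wide regions held by all 6 libraries. Extra copies in the cells or copies merged in the reference would raise the input too. Over all summits of the 83 regions of 10 kb or more, the median background was 1 times its genome-wide minimum in every library. The median pileup was 4.29 to 5.45 times it. Raised input thus did not match the pileup in these called regions. The values cannot test copies further, since peaks were called against this same input. A region whose input rose as much as its pileup would not have been listed. The background was at 1.5 times or more in 7 to 14 of the 83 regions, for which copies stay open. A candidate explanation is read pairs placed far apart, whose span a fragment pileup fills: the outer edges of the 83 regions differed between libraries by a median of 267 bp, although depth ranged from 14.3 to 40.4 M fragments; 63.9% of 166 edges lay within 500 bp, the upper quartile was 1373 bp, and 18 edges differed by over 5 kb, which this leaves unaccounted for. In the top-ranked region on chromosome 2, the pileup fell with distance from the block of highest pileup at 98662755 to 98667210, with Spearman correlations across summits of −0.998 or stronger in all 6 libraries. In that block the background from the input stood at 1371 to 9640 times its genome-wide minimum, so copies stay open there. No biological explanation was tested, since FLAG and IgG libraries hold these regions alike.

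The second pattern is the regions held by FLAG and not by IgG. For each of the 10 splits of the 6 libraries into 3 and 3, the larger of the 2 directed counts was taken. The split into FLAG and IgG was included. For all 3 libraries of a side, 9 of the 10 splits gave as many regions (6, highest other 50). For at least 2 libraries of a side, 5 of the 10 did (194, highest other 325). Both highest counts came from the split of FLAG 2, FLAG 3 and IgG 1, the libraries with the most fragments, against the rest. Taking the larger count favours a high share, and with 10 splits no share under 0.05 can be had. Longer lists from the deeper FLAG 2 and FLAG 3 are a candidate explanation. With 1160 peaks in every list, FLAG still had 1.95 times as many single regions as the mirror count (84 and 43), but these are not independent, since 194 regions formed 71 runs. Counted as loci joined within 50 kb, the ratio was 3.33 with full lists (30 and 9) and 1.25 with equal lists (15 and 12). The counts with equal lists are small. Their intervals, 8.4 to 24.7 for FLAG and 6.2 to 21 for IgG, overlap widely, so a larger ratio is not excluded. With equal lists, 11 of the 20 choices of 3 libraries gave as many joined loci as FLAG. The highest number was 28, for FLAG 2, IgG 1 and IgG 3. List length thus stays open for joined loci and for single regions. Binding of Flag-Zfp697 at a few of these places, such as the 248 kb stretch in Rora, stays open and could not be separated from chance with 3 libraries each. At the Rora regions held by all 3 FLAG libraries, the FLAG 1 peaks had pileups of 11 and 12 fragments. Their −log10 q values of 1.19 and 1.36 lay close to the calling threshold. Whether read pairs placed far apart fill the stretch in Rora was not tested.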
